A study of Caenorhabditis elegans with 4 samples.

How the data were processed

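Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans embryos of strain OP70, in which an integrated transgene expresses MEP-1 fused to green fluorescent protein (GFP) and a Flag tag. Per the labels' protocols, worms were grown in liquid culture with bacteria at 20 °C, crosslinked with 2% formaldehyde and sonicated, and DNA bound by an affinity-purified goat antibody against GFP was recovered, size-selected and sequenced on the Illumina platform. The series holds 4 libraries, made up of 2 replicates of the anti-GFP ChIP and the 2 matching replicates of input DNA. Nothing in the labels says more on how the replicates were made than that each came from its own extraction.

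The authors deposited 1 list of peaks for the whole series, described by its name as combined. Per the file headers, the coordinates are on genome build WormBase WS180 and the regions were called with PeakSeq, a caller that first marks regions where ChIP reads pile up and then compares ChIP reads with scaled control reads in each. The deposited value of each peak is a q-value, the p-value of that comparison after correction for the number of regions tested. The aligner, the version of PeakSeq, the read filters and the way the replicates were combined are not given in the sources used here. No library has values of its own in the list, so replicates could not be compared, no error between replicates can be given and the depth of each library is unknown. Every spread below is a spread between peaks or between stretches of the genome, and every p-value describes this 1 list. Counting intervals cover counting error only.

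Gene names are not given. The gene table at hand describes assembly WBcel235, which differs from WS180, and builds were not mixed. The tests planned on gene starts, location classes, non-coding genes, sequence words and fixed gene lists (among them partners of MEP-1, germ granule and meiosis genes and tissue markers) were therefore left out. The rule for that case, fixed before the data were examined, was to name the 10 peaks with the lowest q and the 5 densest bins of 100 kb by position. Other positions named were chosen after their values were seen.

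Peak coordinates were read as given, counted from 1 and with both ends included. Each chromosome was taken to end at its last peak. Peaks were assigned by their midpoint to bins of 1 Mb, and a last partial bin shorter than 0.5 Mb was left out. Each of the 6 chromosomes was compared with all others by a two-sided permutation test that shuffled bins (100000 resamples), with Benjamini-Hochberg adjustment over the chromosomes. Centre and arms, the middle 0.5 of each chromosome and the rest, were compared by the same kind of test with bins shuffled within chromosomes. Spacing was tested one-sided against 1000 random placements of the same number of midpoints per chromosome. The relation of q to width was measured across peaks by Spearman's and Pearson's coefficients with permutation p-values. Peaks and bins are not independent replicates. In neighbouring bins of a chromosome the deviations from its mean were correlated (r = 0.33 over 94 pairs), so shuffling bins overstates how firm a difference is.

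Read counts were back-calculated from the q-values. A q-value that is multiplied by its rank and divided by the number of tested regions returns the p-value before correction. With 15494 tested regions, these p-values equalled one-sided binomial tails of whole ChIP and control reads at probability 0.5, to within 1e-10 on the natural log scale, for 11441 of 11448 peaks. The other 7 peaks matched more than 1 pair of counts and were left out of statements on reads. The tail was read as including the observed ChIP count. Control reads recovered in this way are after the caller's scaling and rounding, so they are not raw input reads, and no interval is given for a ratio of ChIP to control.

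On simulated data, the back-calculation returned the simulated number of tested regions (14000) and both counts of all 12153 peaks that had 1 match. The simulated tail also included the ChIP count, so that reading was not checked. The chromosome test called a simulated density of 0.7 on chromosome IV in 20 of 20 runs, a density of 0.8 in 10 of 20, and no chromosome in 20 runs without a difference. In these runs chromosome totals varied by counting error only, and neighbouring bins did not correlate. They therefore do not give the rate of false calls in the real list. With independent bins and a density of 0.65 on IV, shuffled bins called IV in 199 of 200 runs and rotated bins in 0. Alternatives fixed in advance were the better 50% of the peaks by q, bins of 500 kb, covered length in place of peak number, a narrower centre, other distances, placement within 1 Mb bins, log10 values and merging of overlapping peaks. Alternatives added after seeing the data were minimum widths of 50 and 200 bp, an equal scaling of the control, rotation of neighbouring bins, bins of 3 Mb, leaving out each chromosome, and placement that keeps widths and gaps. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.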

Results

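The series asked where MEP-1 binds the genome in embryos. MEP-1 is a zinc-finger protein that acts with the Mi-2 homologue LET-418 and the histone deacetylase HDA-1, and the complex is known for keeping germline genes silent in somatic cells. Binding was read through the GFP tag of a transgenic MEP-1, with 2 ChIP libraries set against 2 input libraries. The combined list held 11448 peaks over the 6 chromosomes, or 114 per Mb. They covered 3285 kb, which is 3.28% of the 100.2 Mb up to the last peak of each chromosome. The median peak was 237 bp wide (quartiles 126 and 375 bp). The q-values ran from 1.48e-156 to 0.00991, with a median of 4.51 on the −log10 scale (lower quartile 2.89).

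Most peaks held a few times more ChIP than control reads. In the 11441 peaks with back-calculated reads, a median of 50 ChIP reads (quartiles 32 and 86) stood against 14 scaled control reads (quartiles 9 and 22). The median ratio of ChIP to control was 3.63 (lower quartile 2.83), and the ratios ranged from 1.41 to 30.7. Peaks were listed by a limit on q, which comes from these same counts. At a given number of reads that limit sets the lowest possible ratio, so the ratios describe the listed peaks only. The peaks together held 806198 ChIP reads. The caller had tested 15494 regions, of which the list kept 73.9%.

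Chromosomes differed in the number of listed peaks per Mb, a measure that also depends on the scaled control. Chromosome III carried the most peaks, 149 ± 26.3 per Mb (SD between 14 bins), against 109 on the other chromosomes. Chromosome II followed with 140 ± 21.3 per Mb (SD, 15 bins). Chromosome IV carried the fewest, 78.8 ± 17.3 per Mb (SD, 17 bins) against 122 elsewhere (0.647 times). Chromosome V had 101 ± 32.7 per Mb (SD, 21 bins), and its single bins ranged from 29 to 169. The permutation test over bins called III and IV (adjusted p = 6e-05 for both), II (adjusted p = 0.001) and V (adjusted p = 0.042). Since neighbouring bins correlated (r = 0.33), the permutation test was repeated with bins of 3 Mb, which called III and IV (adjusted p = 0.015 and 0.0024) but not II and V (adjusted p = 0.06 and 0.29). A permutation by rotating neighbouring bins called none (lowest adjusted p = 0.33). With 99 rotations its p cannot fall below 0.01, and 1 differing chromosome alone cannot reach an adjusted p below 0.06. The rotation leaves the differences as they are, so its missing calls do not decide.

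The X chromosome was compared with the autosomes in the same test. It carried 111 ± 13.9 peaks per Mb (SD, 18 bins) and the autosomes 115, a difference that the permutation test did not call (adjusted p = 0.67). Chromosome I, at 119.4 ± 14.2 per Mb (SD, 15 bins), was not called by the permutation test either (adjusted p = 0.62). Peaks on X covered 3.65% of the chromosome, and those on III 3.85%, with median widths of 268 and 200 bp.

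Chromosomes also differed in 2 measured properties of the list. Peaks under 50 bp made up 15.9% of the peaks on II, 15.1% on III, 14.3% on V, 10.3% on I, 7.83% on X and 7.44% on IV. The scaled control also differed: in peaks from 300 bp to under 400 bp wide it had a median of 15 reads on II and on III, 17 on V, 20 on I, 23 on X and 25 on IV. ChIP reads in the same peaks had medians between 71 on V and 84.5 on III. With peaks of at least 200 bp only, the permutation test no longer called the differences of II, III and IV (adjusted p = 0.29, 0.055 and 0.055), while V stayed lower (adjusted p = 0.00042). Shuffled 1 Mb bins overstate how firm such a call is, and this setting was not run with 3 Mb bins. In the full list, 3 Mb bins did not call V (permutation test, adjusted p = 0.29). With the control set to the level of IV on every chromosome, the permutation test still called III and V. Their differences from the others were 22.8 and -31.2 per Mb. II and IV were not called (permutation test, adjusted p = 0.51 and 0.091). X lay above the autosomes (100.0 against 85.5 per Mb, permutation test, adjusted p = 0.026). This setting, also run with 1 Mb bins only, raises the control and can only remove peaks. It kept 100% of the peaks on IV, 89.8% on X, 81.3% on I, 72.2% on III, 65.6% on II and 63.0% on V. The rise of X and the larger deficit of V therefore follow in part from the control factors.

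**Figure D1:**
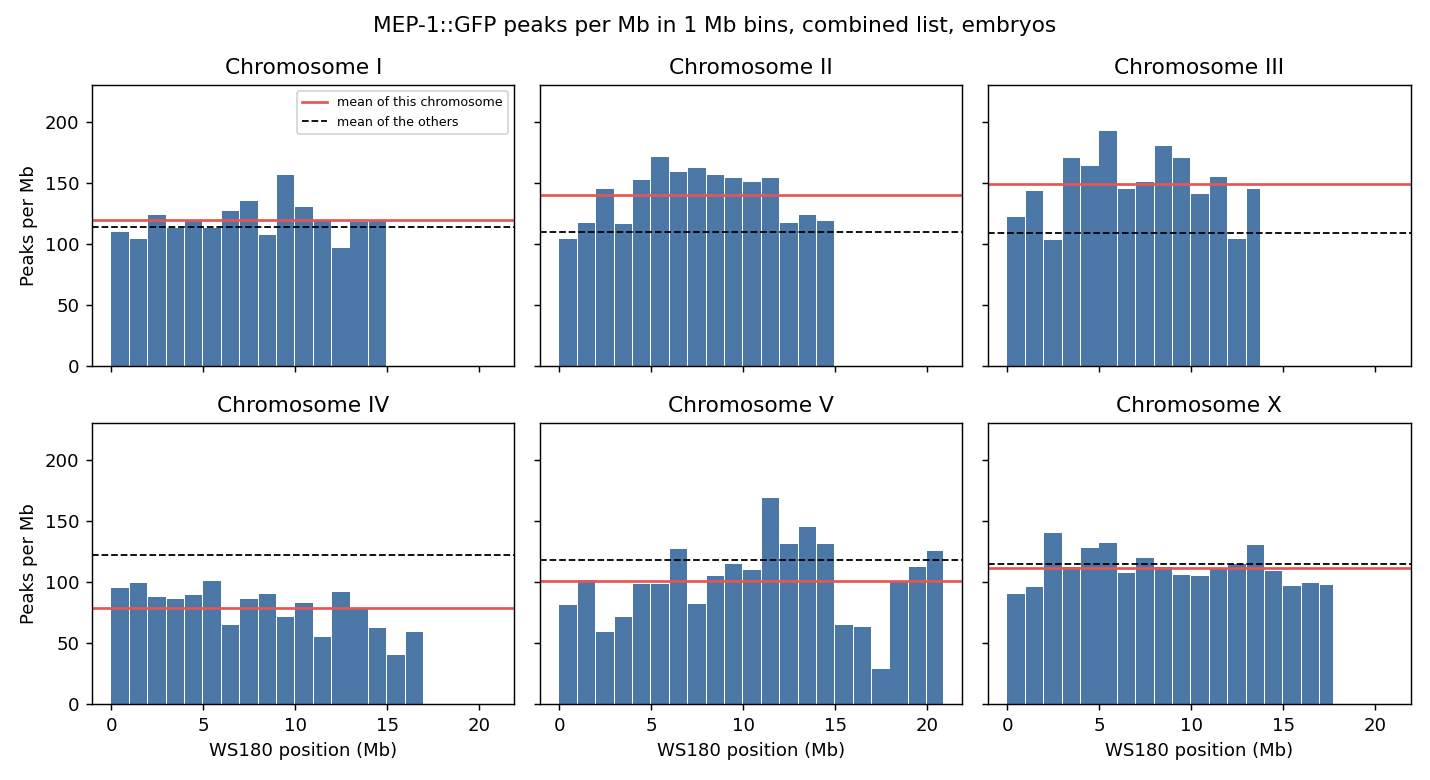
Peaks per Mb (vertical axis) in bins of 1 Mb along each chromosome (horizontal axis, WS180 position in Mb). Bars are single bins, the solid line is the chromosome's mean and the dashed line the mean of the other chromosomes. Bins of chromosome IV stay at or below 101 per Mb, and those of V range from 29 to 169.

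**Figure D2:**
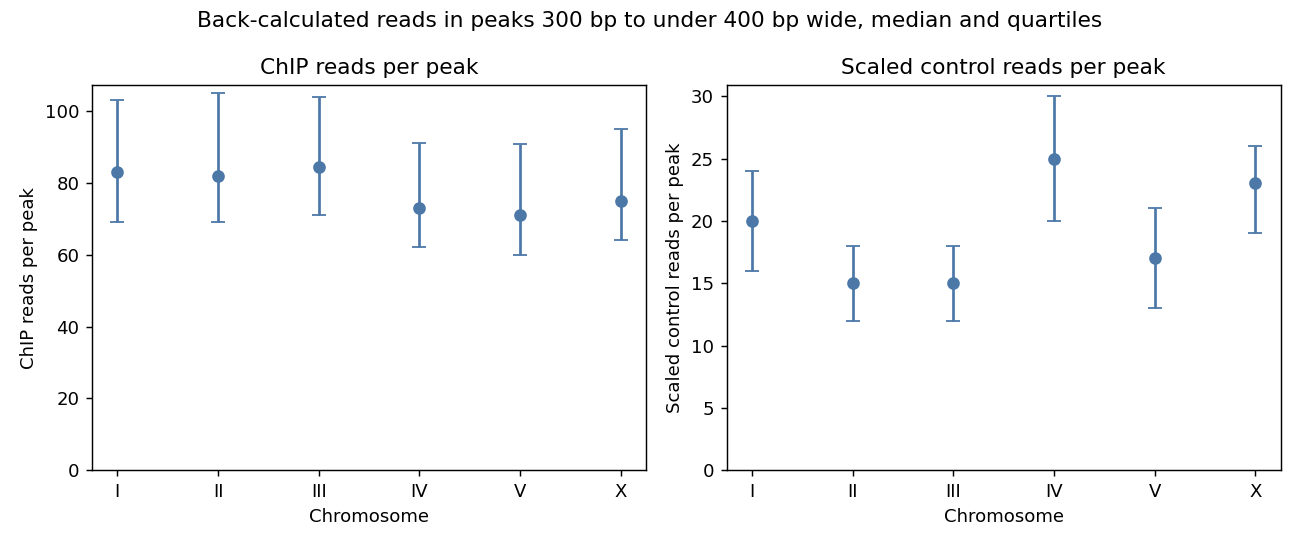
Back-calculated ChIP reads (left) and scaled control reads (right) per peak, for peaks from 300 bp to under 400 bp wide, by chromosome. Points are medians and bars the quartiles. The control medians run from 15 on II and III to 25 on IV, and the ChIP medians from 71 on V to 84.5 on III.

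Chromosome centres carried more peaks per Mb than arms. Worm autosomes have gene-rich centres with little recombination and arms rich in repeats. The middle 0.5 of the chromosomes carried 124 ± 33.0 peaks per Mb (SD, 50 bins) and the outer parts 105 ± 27.5 (SD, 50 bins), a difference of 19.6 per Mb (permutation test within chromosomes, p = 4e-05). Rotation of neighbouring bins within chromosomes, which keeps their correlation, gave a larger p (permutation test, p = 0.0037). The centre was higher on II (158 against 124.5 per Mb, adjusted p = 0.009), on III (167 against 130.4, adjusted p = 0.011) and on V (116 against 84.2, adjusted p = 0.042), by the same permutation test on single chromosomes. The differences on I (13.7 per Mb), X (7.23) and IV (5.46) did not pass the permutation test (adjusted p = 0.081, 0.34 and 0.54). The tests on single chromosomes used shuffled bins only. Whether the chromosomes differ in this contrast was not tested. The pooled difference kept its direction and its call without any 1 chromosome, at 16.7 to 23.5 per Mb, and fell to 12.01 per Mb with the control set to the level of IV. That setting applies 1 factor per chromosome, so it cannot address a control that differs between centre and arms. The control and the mapping of reads in centre and arms were not examined.

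Peaks lay close to each other more often than random placement gave. Another peak midpoint lay within 2000 bp for 51.7% of the peaks, against a mean of 37.6% and a highest value of 39.4% over 1000 random placements (one-sided permutation p = 0.001, the smallest they can give). With placement within 1 Mb bins, which keeps the regional density, the mean was 38.3%. No gap between neighbouring peaks was shorter than 200 bp, and the median gap was 3697 bp.

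The densest stretches lay on chromosome II. The bin from 7800001 to 7900000 held 36 peaks, with a median width of 277 bp. The bin from 6800001 to 6900000 held 35 peaks, which covered 16158 bp, and its lowest q was 3.23e-68. Random placement at the mean density of each chromosome gave at most 34 peaks in any bin, with a median of 26 for the fullest bin of a placement, so the next bins in rank lay above the median and below the highest value. These were 10500001 to 10600000 and 5300001 to 5400000 on II, with 32 peaks each, and 5900001 to 6000000 on III, with 29. At the other extreme, 8 of the 999 full bins of 100 kb held no peak, against at most 2 in random placement, and these 8 bins were on chromosome V. The longest stretch without a peak was 222 kb, from 17316045 to 17538222 on V. How well reads map in these stretches was not examined.

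The strongest peaks by q were broad. Of the 10 with the lowest q, 3 lay on II, 3 on X, 2 on III, 1 on IV and 1 on I, and their widths ranged from 1079 to 3629 bp. The lowest q, 1.48e-156, belonged to a peak on IV from 14032473 to 14034731, with 1002 ChIP reads (95% exact Poisson interval 941 to 1066) against 141 scaled control reads, a ratio of 7.11. The peak on II from 14249097 to 14251971 had 810 ChIP reads and a ratio of 9.88. Chromosome III held a pair of these peaks, 13060912 to 13063069 with a ratio of 10.1 and 13070168 to 13072096 with a ratio of 10.2. The other peaks on II were 11633684 to 11636247 (ratio 8.32) and 9059562 to 9062621 (ratio 6.42). On X, the peaks were 11605064 to 11607023 (ratio 7.32), 16929299 to 16931847 (ratio 7.25) and 10568124 to 10569202 (ratio 10.7). Ratios on different chromosomes are not directly comparable, since the scaled control differed between chromosomes.

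The peak on I among these 10 stood apart. It ran from 15064024 to 15067652, was the last peak of the chromosome and the widest of the list, and held 8899 ChIP reads against 6053 scaled control reads. Its ratio of 1.47 was the 2nd lowest on I, and no other peak held more than 1002 ChIP reads. Its q of 2.86e-117 thus went with a low enrichment over the control and a high depth.

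The q-value followed the width of a peak. Across all 11448 peaks, Spearman's rho between width and −log10 q was 0.80 and Pearson's r was 0.71. Part of this follows from the test itself, since at a given ratio of ChIP to control more reads give a lower q. Within chromosomes rho lay between 0.70 on IV and 0.88 on III. The 1145 peaks with the lowest q had a median width of 539 bp, and the 1145 with the highest q a median of 88 bp. In the list as a whole, 1393 peaks (12.2%) were narrower than 50 bp and 734 narrower than 20 bp.

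**Figure D3:**
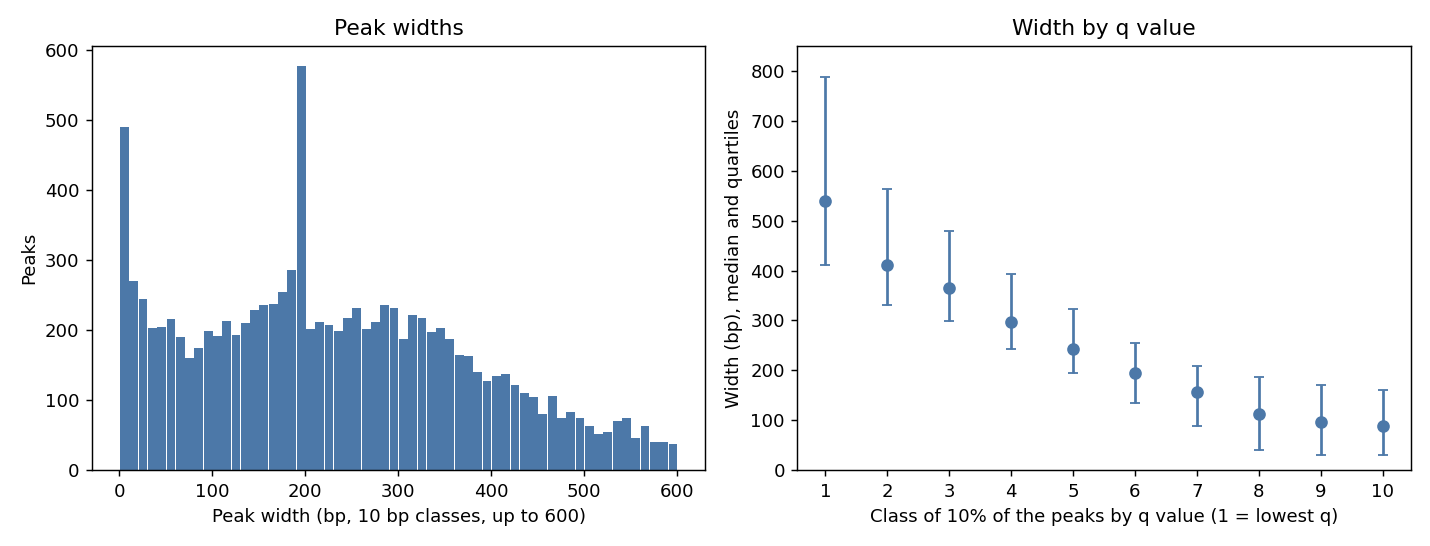
Left, number of peaks (vertical axis) by width in classes of 10 bp, up to 600 bp. Right, median width with quartiles (vertical axis, bp) for 10 classes of equal size ordered by q, from the lowest q (1) to the highest (10); the median falls from 539 to 88 bp. The tallest class, 191 to 200 bp, holds 577 peaks.

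Of the 1145 peaks with the lowest q and the 1145 with the highest, chromosome III held 256 and 121, II 232 and 152, I 182 and 177, X 183 and 264, V 172 and 264, and IV 120 and 167. These counts are given without a test.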

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

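The alternatives with a minimum width, an equal control, rotated bins, 3 Mb bins, placement with widths and gaps, or a chromosome left out were chosen after seeing the data. Of 92 values recomputed, 71 kept their direction and their side of the threshold, or stayed within 1.5 times for counts and medians. Spacing, centre against arms and the relation of q to width did so under every alternative run, although centre minus arms fell from 19.6 to 12.01 per Mb with an equal control. The better 50% of the peaks by q has, by construction, 5724 peaks, with a median width of 362 bp and a median −log10 q of 9.498. Peaks of at least 200 bp numbered 6724, with a median −log10 q of 8.07, and the merging of overlapping peaks joined none. Chromosome II lost its call with peaks of at least 200 bp (5.55 peaks per Mb above the others), with an equal control (4.22) and with covered length (3.26 kb per Mb). Chromosome III lost it with peaks of at least 200 bp (11.8) and IV with these and with an equal control (-11.5 and -11.3). X, not called in the main test, turned from below to above the autosomes with peaks of at least 50 bp (2.65), of at least 200 bp (7.17), with covered length (4.38 kb per Mb) and with an equal control (14.5), and it was called only with the last. The equal control can only remove peaks, and it kept 89.8% of those on X and 63.0% on V. Rotating neighbouring bins leaves the differences of II (30.2), III (40.1), IV (-42.96) and V (-17.1) as they are, and this permutation called none of them (adjusted p = 0.68, 0.33, 0.33 and 0.78). With independent simulated bins and 0.5 times the density on IV, the rotation called IV in 0 of 200 runs, so its lost calls do not decide. Bins of 3 Mb kept III and IV (permutation test, adjusted p = 0.015 and 0.0024) and ended the calls of II (30.7) and V (-16.4). Neighbours among these bins had r = -0.17 over 28 pairs. Deviations from the mean of so few bins per chromosome tend to correlate negatively, so this r does not show that neighbours were independent. The causes were not tested beyond what the weighing of chromosome densities gives. No paired analysis was possible because the list holds no values per library, and no replicate could be left out for the same reason. The depth of the libraries is unknown, and the 4046 tested regions that missed the q limit are not in the list, so no alternative could add a peak.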

Other observations

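The tests on narrow peaks and on the steps of the q-values were chosen after the result was seen; the other tests in this part were written down before theirs, with the equal control and the minimum widths added as settings after seeing the data. Ratios of ChIP to scaled control are compared within chromosomes, since the scaled control differs between them. Among peaks with at least 100 ChIP reads, the highest ratio on I was 16.3, at 14469114 to 14469561, and on II 28.7, at 11759188 to 11759619. It was 30.7 on III, at 8043733 to 8044123 (307 against 10 reads), and 13.6 on IV, at 3294552 to 3294978. On V it was 22.2, at 14055000 to 14055408, and on X 17.1, at 806520 to 806913. These peaks were 391 to 448 bp wide, and none was among the 10 with the lowest q.

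The read counts rest on a hypothesis about the q-values, namely that each is the number of tested regions times a binomial tail of whole reads divided by its rank. With 15494 tested regions, 99.9% of the peaks matched 1 pair of counts, and of the same values moved at random by up to 1%, 0 matched. The values took 3491 distinct steps. The match fixes the total of reads that entered the test and the cut of its tail. It fixes the pair only if the tail includes the observed ChIP count, as was assumed. If it does not, each peak has 1 ChIP read fewer and 1 control read more. How the control was scaled before the test is also left open.

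Chromosome IV had the fewest peaks, and 2 technical candidate explanations were tested: narrow peaks near the calling limit, and a scaled control that is higher on IV. In the better 50% of the peaks by q, IV held 38.5 ± 8.09 per Mb (SD between bins) against 61.04 elsewhere (permutation test, adjusted p = 9e-05), about as far below the others in proportion as in the full list (78.8 ± 17.3 against 122), although q also depends on the control. With peaks of at least 50 bp, a cut that does not use q, it held 73 against 106 (permutation test, adjusted p = 6e-05). Both argue against narrow peaks near the limit as the whole cause. With peaks of at least 200 bp, IV held 57.6 ± 13.7 per Mb (SD between bins) against 69.1 elsewhere (permutation test, adjusted p = 0.055). The smaller difference goes with a part played by peaks under 200 bp, although the cut drops a class with fewer peaks on IV, and that part stays open. With the control set to the level of IV on every chromosome, it held 78.7 ± 17.3 against 89.99 (permutation test, adjusted p = 0.091). Both calls ended because the other chromosomes lost more peaks than IV, which the equal control leaves as it is by construction. In these last settings V and not IV was lowest, at 53.1 and 63.4 per Mb, and in the full list peaks covered 2.67% of IV and of V. A higher control on IV stays open; X, with a control median of 23 against 25 on IV, held 111 peaks per Mb. The same control setting brought II to 4.22 peaks per Mb above the others (permutation test, adjusted p = 0.51), whereas III stayed 22.8 above (permutation test, adjusted p = 0.0012). Shuffled 1 Mb bins overstate how firm this is, and the equal control was not run with 3 Mb bins. Whether a low control is the whole cause of the density of III therefore stays open, also if the control factors hold. Gene content and chromatin of the chromosomes were not tested.

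What differs between chromosomes in the control is itself open. Hermaphrodites carry the autosomes and X in equal copy number, yet the control median in peaks of the same width was 1.67 times higher on IV than on II or III. A scaling factor fitted per chromosome may produce this, as may more input reads on IV, and the list does not separate them. The equal-control setting, which left III called at an adjusted p of 0.0012, takes its factors from the listed peaks alone, and whether they are right was not tested. Ranking by ChIP reads alone instead of q changed the makeup of the 1145 best peaks: X rose from 183 to 243 of them, IV from 120 to 162 and I from 182 to 219, while III fell from 256 to 194, II from 232 to 174 and V from 172 to 153.

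Peaks were closer together than random placement gave, for which 2 technical explanations were tested. If the caller had only split broad regions at gaps of up to 1000 bp, and density were otherwise even, regions joined across such gaps would be spaced at random. Of the 8939 joined regions, 65.0% had another within 5000 bp, above the highest of 1000 random placements (61.7%), which argues against splitting as the whole cause. Uneven density over Mb scales left an excess of 13.4 percentage points within 2000 bp, above all placements within 1 Mb bins. Splitting and uneven density were tested separately, so the 2 acting together were not tested. Clustering of promoters or other regulatory sites, the biological explanation, stays open as untested, since no WS180 gene annotation was used.

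The joined region with the most peaks held 15 in 15060 bp, from 6822247 to 6837306 on II, inside the bin that ranked second in peak number. A width of exactly 200 bp occurred in 253 peaks, against 43 of 199 bp and 22 of 201 bp. Peaks of 200 bp held a median of 43 ChIP reads, and the other peaks of 180 to 220 bp a median of 42. Peaks under 50 bp held a median of 23 ChIP reads (quartiles 22 and 25), near the lowest count of 17 in any peak. On IV the density fell along the chromosome, from 89.9 peaks per Mb in the first of 5 equal parts to 55.5 in the last. The array of ribosomal RNA genes of the worm is known to lie at the right end of chromosome I, the end that held the widest peak, with 2.45 ChIP reads per bp against 0.444 in the peak with the lowest q. The scaled control of the widest peak was high as well, at 6053 reads against 141, and its ratio of ChIP to control was only 1.47.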
